A study of Mus musculus with 5 samples.

How the data were processed

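The series holds 5 single-sample arrays of total RNA from peritoneal macrophages of mice infected with the filarial nematode Brugia malayi, the source of the alternatively activated macrophages that the labels name. By their labels 2 arrays come from wild type mice (replicates b and c) and 3 from mice without a working Il4 gene (replicates a, b and c). The letters are those of the sample titles. No label says that the arrays come from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

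The deposited values are probe set signals, an intensity on a linear scale, from an Affymetrix mouse array recognised by its probe set names. How the authors computed a signal from the single probes, and with what software, is not given in the sources used here. The scale was read from the values, which were all positive and reached 33588. The mean after trimming 2% of the probe sets at each end was 800.5 on each of the 5 arrays, so the arrays had been scaled to each other before they were deposited. A linear scaling of this kind leaves differences in the shape of the distribution: the median signal was 248.7 and 255.6 on the arrays labelled wild type b and c, and 267.9, 278.7 and 270.0 on those labelled IL-4 deficient a, b and c. No detection call was used, so a low signal cannot be told from background except through the floor described next. The number of arrays limits the precision.

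The rule for the main values was written before the data were examined. Because the trimmed means differed by less than 5%, the deposited scaling was kept. Signals under 59.8, the 25th percentile of all values, were raised to that floor, and log2 was taken (floor 5.9). A change against a group that lies at the floor on every array is therefore a lower bound. The 66 Affymetrix control probe sets were left out of the tests, and 9856 probe sets with a signal above the floor on at least 2 arrays were tested. Probe sets were named from the platform's annotation table. Of 12488 probe sets, 10833 had 1 gene symbol (8251 genes), 396 had several and 1193 had none in that table. No gene was named from a probe set with several symbols. The Entrez identifiers of 10817 of them matched the RefSeq gene table, and 0 symbols needed updating. No genome build was named, so no coordinates are given.

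The single comparison was IL-4 deficient minus wild type, by label. It was fitted over all 5 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with 3 residual degrees of freedom, Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given as SE and 95% intervals are limma's moderated ones. As a description without a test, probe sets with a change of at least 2-fold and no overlap between the groups were counted in the labelled split and in the other 9 of the 10 splits of the arrays into 2 and 3. The limma calls of these splits were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 made the tables, and matplotlib 3.10.9 drew the plots.

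Before the data were examined, 25 gene lists were fixed, for macrophage activation states and macrophage origins, cytokine signalling, interferon response, antigen presentation, metabolism, lysosome, matrix, stress, cell cycle, ribosomal proteins, sex-linked genes and the other cell types of the peritoneal cavity. One entry was removed after the annotation was read: Epo had been written for eosinophil peroxidase, and that symbol belongs to erythropoietin. Each list was tested against the rest of the 7006 genes in the list tests with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the one with the highest mean). Camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per array were run beside it. That permutation test cannot give a p below 0.1.

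Genes were named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest changes past the threshold without overlap between the groups. Where fewer pass, it fills up to 10 from probe sets with 1 symbol, at least a 2-fold change, no overlap and the smallest unadjusted p. It also takes 2 to 4 tested members of each list with the largest absolute change (2 are used here), and Il4, Il4ra, Stat6, Arg1, Retnla, Chil3, Mrc1 and Nos2 where a probe set names them. No probe set was named Retnla in the table used. The genes given for the first principal component, and single genes outside this rule, were chosen after their values were seen.

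The fits were tested on simulated data with the real probe sets' means and spread. Over 5 simulated sets of this comparison on 9856 probe sets, 12.4% of the 2-fold changes, 62.1% of the 4-fold changes and 80.3% of the 8-fold changes were recovered, with 30 false calls in all. On 7006 genes, a list shifted 2-fold was called in 19 of 20 runs, and 0 of 480 unshifted lists were called. In these runs the genes varied independently, while the estimated correlation was 0.702 in the real interferon response list and 0.674 in the MHC class II list. The runs therefore do not give the rate of false list calls in the real data.

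The settings listed before the data were examined were quantile normalization, scaling to the 75th percentile, a floor at the 10th percentile, a pseudocount in place of the floor, no filter, a stricter filter, eBayes without the trend or with robust estimation, the letter of the title as a block, leaving out each array in turn, camera with an estimated correlation, and all probe sets of each gene. Leaving out a wild type array leaves 1 array in that group, assumed to vary like the other group. After the data were seen, 3 settings that each leave out a pair of arrays and a crossed block were added, and camera with an estimated correlation was run beside each list call of the other settings.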

Results

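Gene expression was measured on 5 arrays, 1 per RNA sample, from macrophages of the peritoneal cavity of mice infected with Brugia malayi. By label, 2 arrays came from wild type mice and 3 from mice deficient in IL-4, the cytokine that drives alternative activation of macrophages. The comparison asks which transcripts of these macrophages depend on IL-4. Each array held 12488 probe sets. Values are deposited signals, and changes are log2 differences, IL-4 deficient minus wild type by label, with the standard error of limma's fit over 2 and 3 arrays.

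The targeted gene did not follow the labels. On its brightest probe set, Il4 had a signal of 8570 on the array labelled wild type c, but 141 on the array labelled wild type b. Among the arrays labelled IL-4 deficient it had 4900 on a, 7840 on b and 123 on c. Leaving aside the array's control probe set, the second brightest gave 35.2, 2590, 1640, 2700 and 6.04 in the order wild type b and c, then IL-4 deficient a, b and c. The control probe set for mouse Il4 gave 55.4, 7041.5, 4072.4, 6490.0 and 51.2 in that order. A dimmer Il4 probe set was high and low on the same arrays over a smaller range, from 57.5 to 440, and the dimmest stayed between 7.9 and 24.1. The labelled change of the brightest probe set was 0.61 ± 2.29 (SE; 95% interval −4.93 to 6.15; limma adjusted p = 0.986). Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here. Il4 was high on 2 of the 3 arrays labelled IL-4 deficient and low on 1 of the 2 labelled wild type, so it differed within each labelled group. Macrophages need not express Il4, so the low signal on wild type b does not by itself speak against its label. The high signals under the IL-4 deficient label leave the labels in doubt, unless the disrupted gene still gives signal on these probe sets. Every direction that follows is therefore one between labelled groups. Array names are labels throughout.

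**Figure D1:**
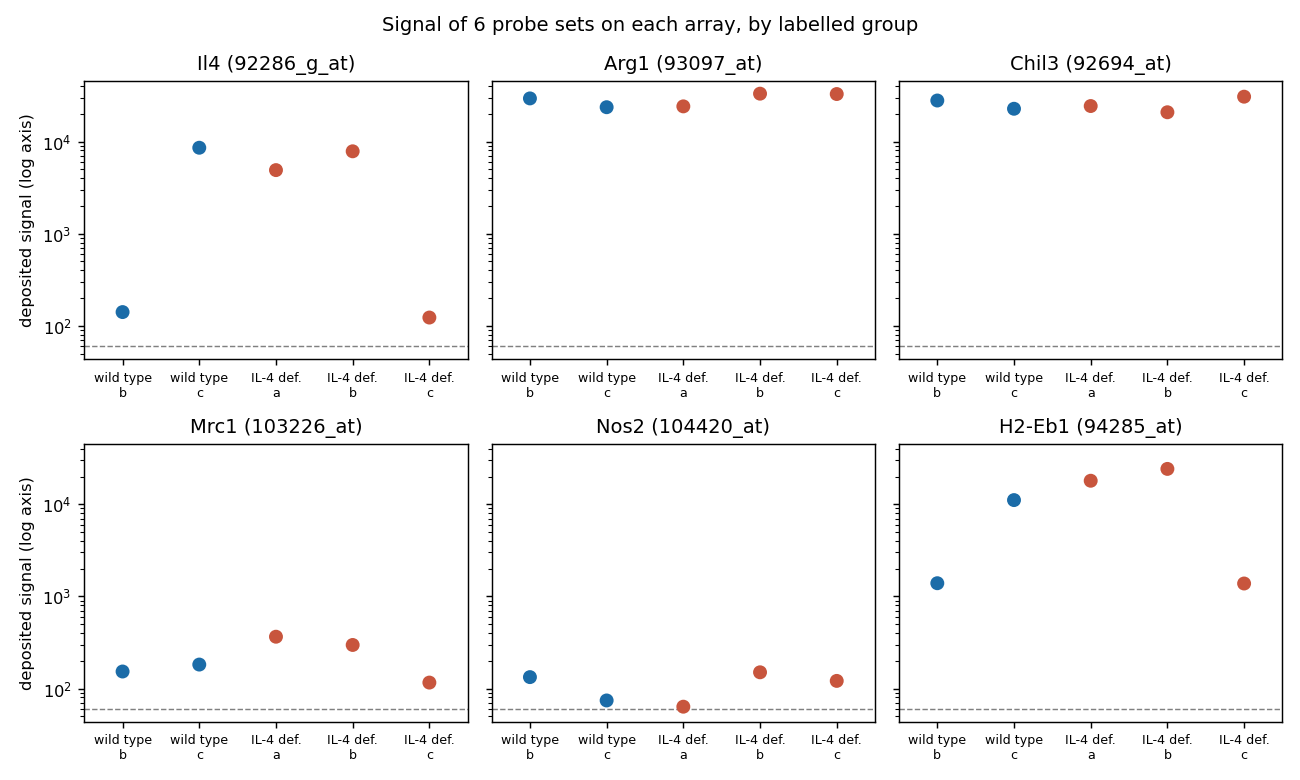
Deposited signal (log axis) of 6 probe sets on each of the 5 arrays, blue for the arrays labelled wild type and red for those labelled IL-4 deficient, with the floor of 59.8 as a dashed line. Il4 and H2-Eb1 are high on the arrays labelled wild type c and IL-4 deficient a and b and low on the other 2, while Arg1 and Chil3 lie between 20800 and 33100 on all 5.

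Arg1 and Chil3, the arginase and the chitinase-like protein (Ym1) that mark alternative activation, were among the brightest probe sets on every array in both labelled groups. Arg1 had signals of 29400 and 23600 on the arrays labelled wild type and 24100, 33100 and 32800 on those labelled IL-4 deficient, a change of 0.17 ± 0.24 (95% interval −0.41 to 0.75; limma adjusted p = 0.95). Chil3 had 27900 and 22700 against 24300, 20800 and 30700, a change of −0.01 ± 0.24 (95% interval −0.59 to 0.57; limma adjusted p = 0.999). Both intervals exclude a change of 2-fold or more between the labelled groups on this signal scale. Arg1 lay at 83.8% to 100% of the highest signal on its array and Chil3 at 62.9% to 91.4%, where a difference can be compressed. The mannose receptor Mrc1 was dim, with a change of 0.48 ± 0.53, and Nos2, the inducible nitric oxide synthase of classical activation, lay between 63.5 and 150 on the 5 arrays, with a change of 0.08 ± 0.47. The change was −0.16 ± 0.15 for Stat6, the transcription factor downstream of the IL-4 receptor, and 0.21 ± 0.22 on the brighter probe set of Il4ra, the receptor's alpha chain. None of these passed the test. Without the array labelled wild type b the Chil3 change was 0.14 and that of Il4 on its brightest probe set was −2.35. Without the array labelled wild type c the Nos2 change was −0.35, and that of Il4 was 3.58.

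Over the whole array, 0 probe sets were higher and 0 lower in the arrays labelled IL-4 deficient at an adjusted p under 0.05 in limma, where the smallest adjusted p was 0.95. At an unadjusted p under 0.05 there were 227 higher and 136 lower among 9856 tested. A change of at least 2-fold without overlap was seen for 114 higher and 58 lower probe sets, 172 in all, of which 26 had a whole group at the floor. Groups did not overlap for 18.1% of the tested probe sets, where chance gives 20%. Under the other 9 splits of the arrays the count of 2-fold differences ran from 99 to 669. The highest count, 669, came from setting the arrays labelled wild type b and IL-4 deficient c against the other 3, which was also the only 1 of the 10 splits with limma calls (361). Counts above the labelled 172 also came from setting wild type c and IL-4 deficient b (179), wild type c and IL-4 deficient a (251), or IL-4 deficient a and b (376) against the rest. The labelled split therefore did not stand out from the others by such counts. With 2 arrays against 3, the 10 splits could in any case give no share under 0.1. Testing all probe sets without a filter gave 2 higher and 6 lower calls. The 2-fold counts were 560 higher and 335 lower without the array labelled wild type c, 192 and 103 without wild type b, 186 and 95 without IL-4 deficient a, and 305 and 135 without IL-4 deficient c. Without IL-4 deficient b they were 135 and 89. Chance non-overlap also rises there, to 50% without a wild type array and 33.3% without an IL-4 deficient one, and limma called 0 probe sets in each.

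**Figure D2:**
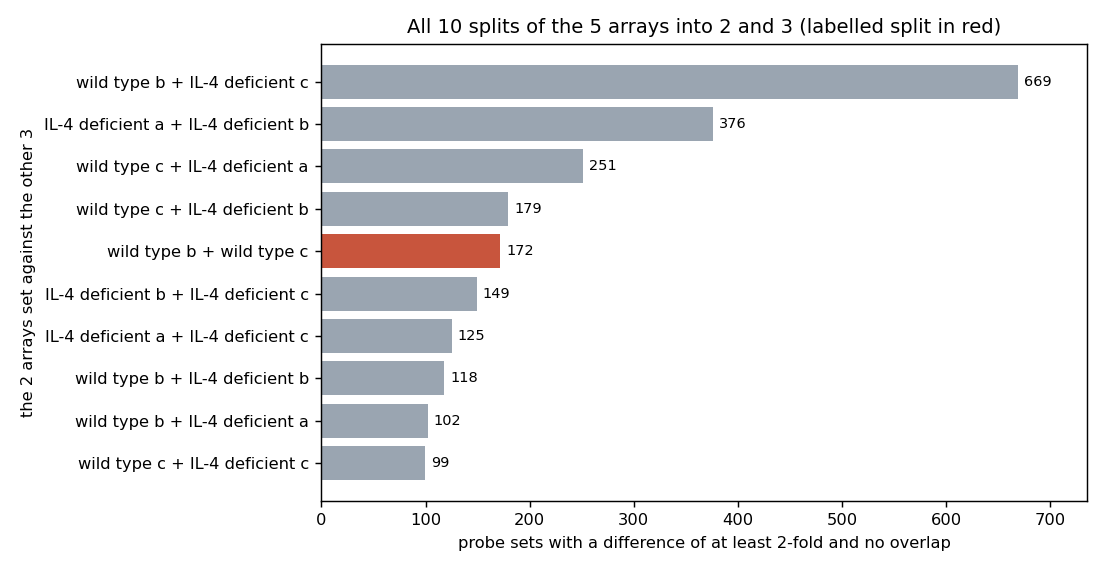
Number of probe sets with a difference of at least 2-fold and no overlap (horizontal axis) for each of the 10 ways to set 2 of the 5 arrays against the other 3 (vertical axis), the labelled split in red. The labelled split gives 172, and the arrays labelled wild type b and IL-4 deficient c against the rest give 669.

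The genes with the smallest p among the 2-fold, non-overlapping differences, none of which passed the test (limma adjusted p = 0.95 for each), were mostly dim. Among those higher by label, Chga (chromogranin A, a secretory granule protein) differed by 1.88 ± 0.42 and Rab3a (a vesicle GTPase) by 1.84 ± 0.39. The other higher values were 1.72 ± 0.39 for the desmosomal cadherin Dsg2, 1.64 ± 0.35 for Otulinl, 1.44 ± 0.31 for Lcat, 1.33 ± 0.29 for Afp (alpha-fetoprotein) and 1.13 ± 0.26 for Zmym4. Syne4, the killer cell receptor gene Klrb1a and the adhesion molecule Mcam lay at the floor on both arrays labelled wild type, so that their folds of 3.09, 2.86 and 2.24 are lower bounds. Among those lower by label, Cela1 (a pancreatic-type elastase) had signals of 565 and 336 on the arrays labelled wild type against 89.7, 98.3 and 132 on those labelled IL-4 deficient, a difference of −2.05 ± 0.36. Tmed9, a protein of the early secretory pathway and the brightest of these genes, had 2670 and 2110 against 1150, 554 and 548, a difference of −1.76 ± 0.36. The netrin receptor Unc5c differed by −1.87 ± 0.39, the keratin Krt1 by −1.79 ± 0.37, Urm1 by −1.76 ± 0.34, Gnasas1 by −1.27 ± 0.29, Pou5f1 by −1.27 ± 0.29, Ocm by −1.16 ± 0.30 and Ada, adenosine deaminase, by −1.12 ± 0.28. Nmb (neuromedin B) lay at the floor on all 3 arrays labelled IL-4 deficient and was at least 2.4-fold lower there. Another probe set of the same gene went the other way for Syne4 (−0.18), Lcat (−0.55), Pou5f1 (0.30) and Ada (0.15), and was smaller for Otulinl (as low as 0.04) and Dsg2 (0.42). Without a filter, the adjusted p of Syne4 was 0.0413.

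Of the 25 gene lists, 0 passed camera's test at an adjusted p under 0.05, and 0 of their members passed in limma, over all genes tested or adjusted over the list alone. The alternative activation list held 20 tested genes, 8 of them also in another list, of which 11 were higher and 9 lower by label, with a median change of 0.11 (camera adjusted p = 0.86; exact permutation p = 1). Its largest differences were in Slc7a2, a transporter that brings arginine into the cell, with −1.0 ± 0.94, and Myc, with 0.98 ± 0.37. Slc7a2 had signals of 15200 and 8900 on the arrays labelled wild type b and IL-4 deficient c, and of 2900, 1360 and 3020 on wild type c and IL-4 deficient a and b. Of 28 genes of classical activation 15 were higher and 13 lower, with a median of 0.04 and a mean of 0.21, while camera's direction was down (adjusted p = 0.86). The scavenger receptor Marco differed by 1.86 ± 1.78 and the interferon-induced chemokine Cxcl9 by 1.48 ± 1.1. The list of IL-4 receptor signalling had 8 of 16 genes higher and a median of −0.01 (adjusted p = 0.86), and Il13ra1, a chain of the receptor for IL-13, differed by 0.66 ± 0.48.

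The mean of the interferon response list, in log2 relative to the 5 arrays, was −0.71 and 0.57 on the arrays labelled wild type b and c and 0.49, 0.51 and −0.85 on IL-4 deficient a, b and c. That of the MHC class II list was −0.70, 0.15, 0.53, 0.81 and −0.79 in the same order. Of 29 interferon response genes 16 were higher and 13 lower by label, with a median of 0.06 and a camera direction of down (adjusted p = 0.998). Iigp1 and Irgm1, interferon-inducible GTPases, differed by 1.57 ± 2.18 and 1.51 ± 1.07. Iigp1 had signals of 102 and 2860 on the arrays labelled wild type b and c, and 6060, 6780 and 99.4 on IL-4 deficient a, b and c. Of 13 MHC class II genes 12 were higher by label, with a median of 0.45 (camera adjusted p = 0.156, and adjusted p = 0.938 with an estimated correlation). H2-Eb1, a class II beta chain, had signals of 1390 and 11100 against 18000, 24200 and 1380, a difference of 1.1 ± 1.41, and H2-Oa differed by 0.99 ± 0.34. In the B cell list 14 of 19 genes were higher by label, with a median of 0.40 (camera adjusted p = 0.0587, and adjusted p = 0.938 with an estimated correlation). Cd22, a B cell receptor inhibitor, differed by 1.60 ± 0.47 and the immunoglobulin gene Iglc1 by 1.28 ± 0.44. The interferon and MHC class II lists were called only with arrays left out. The B cell list also passed camera with all 5 arrays under quantile normalization (adjusted p = 0.0386), 75th percentile scaling (0.0254), a pseudocount (0.0414) and all probe sets of each gene (0.0142). The interferon list was down without the array labelled wild type b (median −0.34, adjusted p = 0.000869) and up without IL-4 deficient c (median 0.29, adjusted p = 0.0131), which also brought the MHC class II list (median 0.81, adjusted p = 4.37e-05) and the B cell list (median 0.42, adjusted p = 0.00545) past the threshold. With an estimated correlation these calls were lost (adjusted p = 0.955 without wild type b, and adjusted p = 0.945 for each of the 3 lists without IL-4 deficient c). Over all settings, with either correlation, the adjusted p ran up to 0.999 for each of the 3 lists. The actin 3' to 5' signal ratio, a measure of RNA quality, was 0.75 and 0.45 on the arrays labelled wild type b and c and 0.59, 0.76 and 0.87 on IL-4 deficient a, b and c, and the Gapdh ratio was 0.73, 0.66, 0.69, 0.77 and 0.79 in that order. Within each labelled group both ratios were lower on the arrays with the higher interferon and MHC class II signals.

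**Figure D3:**
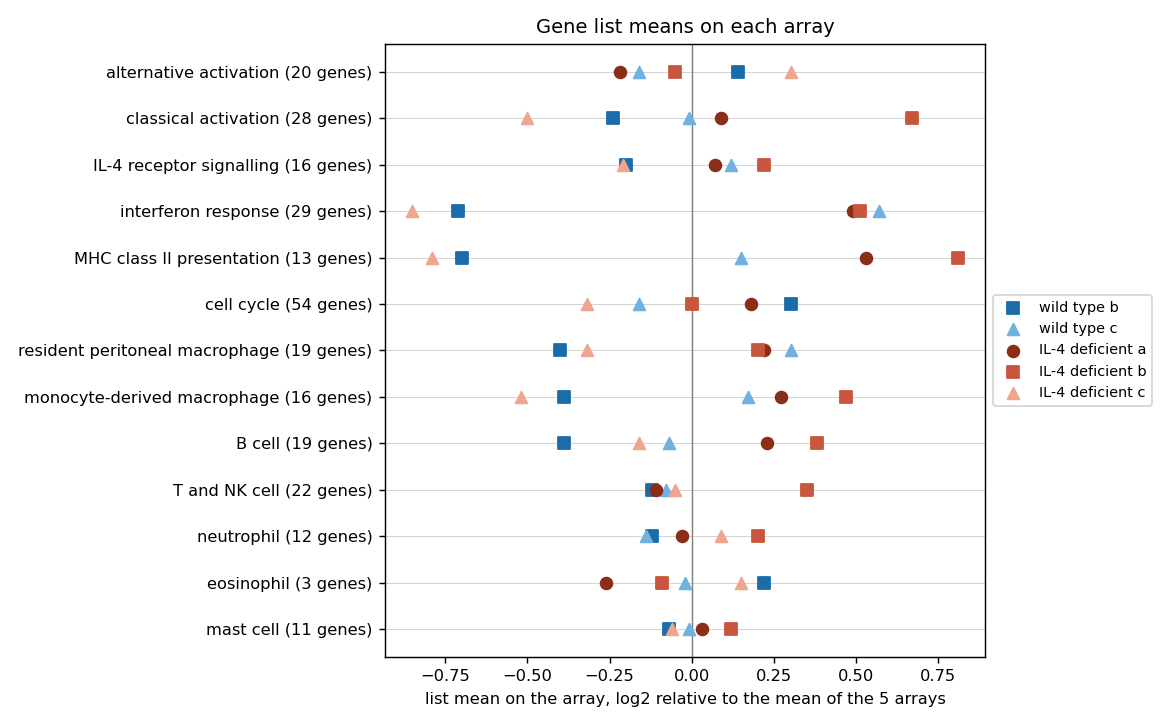
Mean of 13 gene lists on each array (horizontal axis, log2 relative to the mean of the 5 arrays), blue for arrays labelled wild type and red for those labelled IL-4 deficient, with the letter of the title as the symbol. The interferon response list lies at −0.71 and −0.85 on the arrays labelled wild type b and IL-4 deficient c and between 0.49 and 0.57 on the other 3.

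Macrophage origin lists and other cell types gave no call. Genes of resident peritoneal macrophages were higher in 15 of 19 cases, with a median of 0.12 (camera adjusted p = 0.86). Gata6, the transcription factor of these cells, differed by −0.73 ± 0.30 on its brightest probe set and by up to 0.50 on another, and Ltbp1 by 0.55 ± 0.94. Of 16 genes of monocyte-derived macrophages 9 were higher, with a median of 0.06 (adjusted p = 0.86), and Plac8 and the lysozyme gene Lyz2 differed by 0.90 ± 1.13 and 0.87 ± 0.46, the latter by 0.12 on another probe set. The neutrophil list had 9 of 12 genes higher and a median of 0.21 (adjusted p = 0.531), led by Mpo, myeloperoxidase, with 0.79 ± 0.25 and Itgb2l with 0.64 ± 0.29. T and NK cell genes had a median of 0.09 (13 of 22 higher; adjusted p = 0.833), with 1.26 ± 0.45 for the granzyme gene Gzmb and 1.09 ± 0.53 for Cd2. Dendritic cell genes had 0.15 (6 of 8 higher; adjusted p = 0.608), with 0.78 ± 0.26 for Flt3 (0.02 on its other probe set) and 0.34 ± 0.27 for Fscn1. Only 3 eosinophil genes were tested, with a median of −0.19 (1 higher; adjusted p = 0.86), and Ccr3, the eotaxin receptor, differed by −0.52 ± 0.31 and Gata1 by 0.22 ± 0.25. Mast cell genes had a median of 0.02 (6 of 11 higher; adjusted p = 0.86), with 0.70 ± 0.37 for Slc6a4 and 0.59 ± 0.44 for Rprm. Mesothelial and stromal genes had 0.01 (10 of 19 higher; adjusted p = 0.86), with the collagens Col1a1 at 1.33 ± 0.55 and Col3a1 at 0.81 ± 0.26. Erythroid and platelet genes had 0.08 (5 of 8 higher; adjusted p = 0.86), with Car2 at 0.67 ± 0.33 and the globin Hba-a1 at 0.31 ± 0.46.

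Cell cycle genes were lower by label in 35 of 54 cases, with a median of −0.12 (camera adjusted p = 0.059, and adjusted p = 0.938 with an estimated correlation; exact permutation p = 0.7). Rrm1, a subunit of ribonucleotide reductase, differed by −0.87 ± 0.46 and the mitotic kinase Aurkb by 0.92 ± 0.61. This list passed the threshold without the array labelled wild type c (median −0.41, adjusted p = 0.000114) and without IL-4 deficient a (median −0.25, adjusted p = 0.000117), and under quantile normalization (median −0.20, adjusted p = 0.0386), each time lower by label. It passed in the opposite direction, higher by label, without the arrays labelled wild type b and IL-4 deficient c, a setting chosen after seeing the data (median 0.21, adjusted p = 0.0036), and its median was 0.05 without wild type b alone (adjusted p = 0.41). With an estimated correlation these 4 calls were lost (adjusted p = 0.958, 0.949, 0.981 and 0.928 in that order). Over all settings, with either correlation, the adjusted p of this list ran from 3.93e-06 to 0.999, with calls in both directions. Ribosomal protein genes were higher in 24 of 31 cases, with a median of 0.07 (adjusted p = 0.608), with Rpl38 at 0.89 ± 0.30 and Rpl7l1 at 0.64 ± 0.30, and this list passed without the array labelled wild type b (median 0.26, adjusted p = 0.000851, but adjusted p = 0.91 with an estimated correlation).

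Metabolic and secreted-protein lists had medians near 0. Fatty acid oxidation and lipid handling had 16 of 32 genes higher and a median of −0.01 (mean 0.08; camera adjusted p = 0.86), with the lipase Lpl at 0.94 ± 1.17 and the dehydrogenase Acadl at 0.92 ± 0.40. Glycolysis had 9 of 15 higher and a median of 0.11 (mean −0.01; adjusted p = 0.998), with Aldoc at −0.65 ± 0.76 and Pfkl at −0.34 ± 0.31. Chemokines had 10 of 21 higher and a median of −0.05 (mean 0.03; adjusted p = 0.86), with Cxcl10 at 1.22 ± 0.60. Complement and coagulation had 14 of 22 higher and a median of 0.09 (adjusted p = 0.86), with the complement factor Cfb at 0.71 ± 0.40 and C9 at −0.71 ± 0.25. Lysosomal genes had 15 of 34 higher and a median of −0.02 (adjusted p = 0.833), with the protease Ctsc at 0.58 ± 0.39 (as low as 0.16 on another probe set) and Gla at −0.42 ± 0.37. Matrix remodelling and growth factors had 14 of 30 higher and a median of −0.04 (adjusted p = 0.86), with Vegfa at −0.77 ± 0.47 and Loxl1 at 0.64 ± 0.51. Immediate early and heat shock genes had 16 of 34 higher and a median of −0.11 (adjusted p = 0.833), with the heat shock gene Hspa1b at 0.91 ± 0.69. The sex-linked genes had a median of 0.04 over 3 genes (adjusted p = 0.86), with Sry at 0.76 ± 0.31 and Uty at −0.54 ± 0.34.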

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

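The settings that leave out a pair of arrays, and the crossed block, were chosen after seeing the data. All others were planned. Genes near the floor of 59.8 carry little information. No limma call was made in any setting except 2: without a filter 2 probe sets were higher and 6 lower (range of the smallest adjusted p over all settings 0.00206 to 1), and with the crossed block 2 were lower. The 8 without a filter, named after their values were seen, were Syne4, Lama5, Apoc4, Clec4a2, Six4, Tnfsf10, Gas2 and Tyrp1. All 8 were also tested under the main filter, and the fit without a filter had 0.76 prior degrees of freedom in place of 3.26. Why the calls appeared was not tested further. Quantile normalization moved the split of 2-fold differences to 86 higher and 78 lower, from 114 and 58.

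Both groups share only the letters b and c. Arrays of 1 letter deviated from their group means in opposite directions over probe sets (correlation −0.26 for b and −0.46 for c), but with 2 wild type arrays the deviations of b and c mirror each other, so this does not show what the letters mark. The letters were not taken to pair the arrays. With the letter as a replicate block, limma called 0 higher and 0 lower, with 137 and 65 2-fold differences. In that block the change was −0.16 for the brightest Il4 probe set and 0.01 for Chil3, and the list medians were −0.11 for interferon response, 0.01 for eosinophil, −0.02 for mast cell, 0.02 for matrix remodelling and −0.05 for sex-linked genes, all of the opposite sign. The cell cycle list passed there (median −0.25, adjusted p = 3.93e-06, and adjusted p = 0.951 with an estimated correlation). Crossing the letters (wild type b with IL-4 deficient c, wild type c with IL-4 deficient b) gave 0 higher and 2 lower calls, Tmed9 and Scx, the latter named after its values were seen.

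The 2-fold counts, higher and lower, were 276 and 156 with a floor at the 10th percentile, 56 and 22 with a pseudocount, and 24 and 8 with the stricter filter, which tests fewer probe sets. They were 805 and 519 without both arrays of letter c, 238 and 113 without wild type b and IL-4 deficient c, and 386 and 282 without IL-4 deficient a and b, where chance non-overlap is 66.7%. Leaving out 1 array gave 135 to 560 higher and 89 to 335 lower.

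List medians changed sign as follows, and the cause was not tested. With quantile normalization they were −0.01 for mast cell, −0.01 for T and NK cell, −0.05 for mesothelial, −0.04 for erythroid, 0.01 for IL-4 receptor signalling and −0.02 for ribosomal protein, and Nos2 was at −0.06. With 75th percentile scaling they were −0.01 for mast cell and −0.03 for mesothelial. With the lower floor they were 0.09 for eosinophil, −0.04 for mast cell, 0.12 for chemokines and 0.03 for IL-4 receptor signalling. A pseudocount gave 0.01 for chemokines and 0.02 for IL-4 receptor signalling, and the stricter filter −0.04 for classical activation and 0.01 for IL-4 receptor signalling. All probe sets of each gene gave 0.01 for fatty acid oxidation, 0.01 for IL-4 receptor signalling and 0.02 for immediate early genes.

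Without both arrays of letter c the medians were −0.19 for alternative activation, −0.02 for mast cell, −0.21 for mesothelial, −0.39 for erythroid, −0.23 for glycolysis, 0.32 for chemokines, −0.06 for complement, 0.04 for lysosome, 0.10 for matrix remodelling and −0.09 for ribosomal protein. Without wild type b and IL-4 deficient c they were 0.21 for cell cycle, 0.05 for fatty acid oxidation, 0.03 for matrix remodelling and 0.01 for IL-4 receptor signalling. Without IL-4 deficient a and b they were −0.46 for classical activation, −0.73 for interferon response, −0.53 for MHC class II, −0.22 for monocyte-derived macrophage, 0.32 for eosinophil, −0.04 for T and NK cell, 0.01 for fatty acid oxidation, 0.03 for matrix remodelling, 0.16 for immediate early genes and −0.21 for sex-linked genes.

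Leaving out 1 array at a time, list medians ran from −0.05 to 0.03 for IL-4 receptor signalling, −0.07 to 0.27 for T and NK cell, −0.01 to 0.19 for alternative activation, −0.41 to 0.05 for cell cycle, −0.14 to 0.20 for chemokines, −0.08 to 0.18 for classical activation and −0.07 to 0.21 for complement. They ran from −0.47 to 0.01 for eosinophil, −0.23 to 0.35 for erythroid, −0.15 to 0.16 for glycolysis, −0.16 to 0.11 for immediate early genes, −0.34 to 0.47 for interferon response, −0.07 to 0.05 for lysosome, −0.02 to 0.18 for mast cell and −0.05 to 0.07 for matrix remodelling. The remaining ranges that cross 0 were −0.13 to 0.23 for mesothelial, −0.05 to 0.34 for monocyte-derived macrophage, −0.10 to 0.15 for resident macrophage, −0.09 to 0.26 for ribosomal protein and −0.11 to 0.20 for sex-linked genes.

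Leaving out the array labelled wild type b or wild type c set both ends of the gene ranges: −2.35 to 3.58 for the brightest tested Il4 probe set, −2.01 to 3.43 for the second, −0.48 to 2.02 for the third, −0.16 to 0.14 for Chil3, −0.35 to 0.50 for Nos2, −2.20 to 0.20 for Slc7a2, −0.84 to 3.97 for Iigp1, −0.23 to 3.25 for Irgm1 and −0.40 to 2.60 for H2-Eb1. Likewise they were −0.14 to 1.98 for Aurkb, −0.91 to 2.02 for Ltbp1, −0.59 to 2.39 for Plac8, −0.27 to 0.89 for Hba-a1, −0.36 to 2.24 for Lpl, −1.80 to 0.49 for Aldoc, −0.84 to 0.16 for Pfkl, −1.55 to 0.01 for Vegfa and −0.20 to 2.01 for Hspa1b.

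The B cell list, with a median above 0 in each setting, passed under quantile normalization (adjusted p = 0.0386), 75th percentile scaling (0.0254), a pseudocount (0.0414) and all probe sets of each gene (0.0142), within a range of adjusted p, with either correlation, from 0.00545 to 0.999. The cell cycle list passed with a pseudocount (adjusted p = 0.0414) and the stricter filter (0.0452). Without both arrays of letter c, camera called interferon response (median 0.67, adjusted p = 3.23e-07), MHC class II (1.34, 0.000259) and B cell (0.80, 0.0327) higher and cell cycle (−0.26, 0.0327) lower. Without wild type b and IL-4 deficient c it called MHC class II (0.41, 0.00111), cell cycle (0.21, 0.0036), B cell (0.47, 0.00864) and ribosomal protein (0.22, 0.00864) higher. Without IL-4 deficient a and b it called interferon response (−0.73, 4.12e-05) and cell cycle (−0.41, 1.18e-05) lower. With an estimated correlation every list call of the settings given here was lost, with adjusted p from 0.828 to 0.981. That test rests on 3 residual degrees of freedom or fewer, so the loss does not show that correlation made the calls. Over the settings listed before the data were examined, wherever a named gene was tested, 1007 values kept their side of the threshold and their direction, 28 took the opposite sign and 1, Syne4 without a filter, passed. This tally is partly fixed by the choice of genes and does not measure robustness. No named gene passed in the main fit, and genes picked for non-overlapping groups cannot change sign when 1 array is left out.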

Other observations

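All tests in this part, except the counts of 2-fold differences over the 10 splits, were chosen only after the result was seen, and so were the genes named for the first principal component. The largest component of variation among the arrays did not follow the labels. The first principal component of the tested probe sets took 51.5% of the variance, with scores of −0.64 and 0.25 for the arrays labelled wild type b and c and 0.43, 0.39 and −0.43 for IL-4 deficient a, b and c. Its positive end was led by Iigp1, Il4, Marco, Apoc2, Acod1 (the itaconate-producing enzyme), Fpr2 (a formyl peptide receptor), Cp (ceruloplasmin) and H2-Eb1. Acod1 had signals of 194 and 2010 on the arrays labelled wild type b and c, and 2170, 6320 and 154 on IL-4 deficient a, b and c, and Apoc2 had 236, 2640, 3920, 3870 and 78.3 in that order. The chemokine Ccl5 had 18.9, 241, 441, 783 and 19.7.

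At the negative end lay the inflammatory cytokine Il6, with 13900 and 1180 on the arrays labelled wild type b and c and 1090, 1680 and 9320 on IL-4 deficient a, b and c. Il1a had 8310, 1270, 558, 1200 and 3010 in that order, the acute phase gene Saa3 had 23400, 5880, 2610, 5140 and 23200, and Sprr2f had 1460, 74.0, 24.4, 83.8 and 1730. Against 10000 random lists matched on expression, the median score along this component of the interferon response list stood at percentile 100, with 28 of 29 genes positive. The MHC class II list (12 of 13 positive) and the B cell list (15 of 19 positive) also stood at percentile 100, the chemokine list at 99.9, classical activation at 98.9 (16 of 28 positive), resident peritoneal macrophage at 98.8 and monocyte-derived macrophage at 96.4. Alternative activation stood at 4.8 (13 of 20 negative), glycolysis at 3.6 (12 of 15 negative) and immediate early and heat shock genes at 0.4 (23 of 34 negative). These percentiles describe these arrays only. The genes of a random list were drawn independently, while those of the real lists vary together (estimated correlation 0.702 for interferon response and 0.674 for MHC class II). Lists whose genes vary together tend to lie at an end of a leading component, so the percentiles are not p-values.

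Il4 signal was high on 3 of the 5 arrays, in both labelled groups. RNA quality stays open: the actin 3' to 5' ratio was 0.45, 0.59 and 0.76 on the arrays with high Il4 and 0.75 and 0.87 on the others, and within each labelled group the actin and Gapdh ratios were lower on every array with high Il4, by 0.11 to 0.30 and by 0.02 to 0.10. Over all 5 arrays the ratios did not follow Il4. Actin and Gapdh were at 0.76 and 0.77 on IL-4 deficient b, where Il4 was high, and at 0.75 and 0.73 on wild type b, where it was low. An exchange of the labels of wild type c and IL-4 deficient c is a candidate explanation that stays open. The split it implies gave 669 2-fold differences, against 172 as labelled and 376 for the highest other split. This points to a structure of the samples, but 10 splits are too few for a share under 0.05. The exchange alone would put every array with high Il4 under the IL-4 deficient name. Whether that speaks against the exchange depends on whether a disrupted allele gives signal on these probe sets, which is not known here. Other wrong labels, and transcript from a disrupted Il4 allele, also stay open and were not tested. Other cells that make Il4 cannot be excluded: within a labelled group their lists were higher on an array with high Il4 by at most 0.40 ± 0.17 (SE over genes), while the eosinophil list went as far as −0.42 ± 0.33 in the other direction, against at least 4.78 for the 2 brightest tested Il4 probe sets and 1.25 to 2.50 for the third, but 20 of their 36 genes lay within 1 log2 unit of the floor.

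MHC class II genes were higher on the arrays with Il4 signal within each labelled group, by 0.85 ± 0.31, 1.31 ± 0.34 and 1.60 ± 0.34 (SE over genes) in the 3 pairs. The B cell list differed in the same pairs by 0.33 ± 0.15, 0.39 ± 0.15 and 0.54 ± 0.15. These errors measure the spread over the genes of a list, not between samples, and the pairs labelled IL-4 deficient share array c. The smallest excess of the MHC class II list over the B cell list, in the pair labelled wild type, was 0.52 ± 0.34, less than 2 standard errors. The gap was wider in the 2 pairs labelled IL-4 deficient (1.31 against 0.39, and 1.60 against 0.54). Because the excess was not clear in each pair, B cells on those arrays stay open as a cause. RNA quality and a response of the macrophages stay open too and were not tested for these genes. The actin and Gapdh ratios moved with the same arrays within each labelled group but not over all 5 arrays. They were 0.76 and 0.77 on IL-4 deficient b, where these genes were high, and 0.75 and 0.73 on wild type b, where they were low.

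Arg1 and Chil3 had a like level in both labelled groups. Whether a difference was compressed near the top of the scale cannot be told apart from equal levels, because the lowest share of the highest signal, Chil3 on the array labelled IL-4 deficient b, was 62.9% and all other values of both genes were at or above 83.7%. If labels were wrong, the labelled comparison of these genes would not be one between the genotypes, which stays open.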
